A study of Danio rerio with 4 samples.

How the data were processed

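Coronary endothelial cells of wild-type zebrafish were sorted from cryoinjured ventricles at 7 days after injury into 2 gates, with 2 libraries each. Per the labels' protocols, about 5 ng of total RNA per library was amplified with a SMART-Seq v4 low-input kit into full-length cDNA, before fragmentation and library preparation. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.11a, Picard 3.1.1, featureCounts 2.0.4 and DESeq2 1.36.0 and the build danRer11 were used, with no role or order given. The deposited table holds normalized gene counts that the authors rounded to whole numbers, a unit recorded as score because it is neither raw counts nor a rate. That each library was divided by 1 size factor is read from the values: whole numbers are skipped or doubled at regular steps, so the worth of 1 read could be estimated per library as 0.9205 and 0.9935 in Regenerating and 0.9926 and 1.0844 in Non-Regenerating. These steps gave read totals between 9741978 and 11583307. Values in 1 library, Regenerating replicate 1, traced back to a single read number for 85.1% of genes, and in the other libraries for at least 99% of genes. The highest value of any gene was 0.148% of its library's total.

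The table lists 20306 genes with Ensembl identifiers, symbols and coordinates. The mitochondrially encoded list of 13 genes matched 0 rows and was not tested. Column headings were matched to samples by the gate that the headings are taken to name, as stated with the results, and no column of values was left unused. Replicates had correlations of log2 values across genes of 0.942 in Regenerating and 0.945 in Non-Regenerating, against 0.891 to 0.921 between groups, where genes are not independent replicates.

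The tests, lists, filters and named genes were fixed before the data were examined. Genes with a value of at least 10 in at least 2 of the 4 libraries entered, which left 16928. Values were taken as log2(value + 1), so that folds of low genes are understated, and were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 2 residual degrees of freedom, 3.08 prior degrees of freedom). Benjamini-Hochberg adjusted p under 0.05 called a gene. Because the values are not raw counts, no count model was used. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over 23 lists. List members were also adjusted over the list alone. The 24 lists held 667 names, of which 612 were found. A name that matched more than 1 row was left out. The lists were pan-endothelial, arterial and Notch, venous and lymphatic, tip cell and angiogenic sprouting, endocardial, cardiomyocyte, epicardial and fibroblast, mural cell, macrophage and monocyte, neutrophil, lymphoid cell, erythrocyte and thrombocyte, cell cycle, extracellular matrix and basement membrane, inflammatory cytokine and adhesion, interferon response, TGF-beta and BMP signalling, mesenchymal transition, hypoxia and glycolysis, fatty acid uptake and metabolism, lysosome, immediate early and dissociation stress, ribosomal protein and mitochondrially encoded. They share some genes, and 565 different genes were tested.

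Genes were named by a rule: flt1, cxcr4a and gpnmb; up to 12 called genes in each direction with the largest change, a mean of at least 50 and no overlap between groups; and in each list the 3 tested members with the smallest unadjusted p. Only 1 called gene met the second part. Other genes are said to have been chosen after their values were seen, apart from members counted as passing adjustment over their list. Group values are means ± SD, and folds come from the log2(value + 1) fit. For genes at 0 in both Non-Regenerating libraries, folds were taken against a floor of 3 reads per library, which covers counting error only, since reads carry no molecular identifiers.

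The gene fit was tested on simulated data with 16928 genes and 5 runs of 200 changed genes. Means were those of the real genes, and variances were drawn from the prior that limma fitted, so the data followed limma's own model. For the Regenerating against Non-Regenerating comparison it called 1.2% of genes changed by a log2 of 1, 29.2% at 2, 66.4% at 4 and 82% at 6, and 0.0275% of unchanged genes. The camera test called 25 of 25 simulated lists of 25 genes shifted by a log2 of 1 and 1 of 90 unshifted lists. It called 0 of the 25 with an estimated correlation, so such calls are hard to reach with 2 libraries per group. The simulated genes varied independently, whereas the estimated correlation was 0.687 in the cardiomyocyte list and 0.533 in the macrophage and monocyte list. The 1 of 90 therefore does not measure false calls at the preset correlation in such lists. Alternatives were the replicate block, other filters, pseudocounts and scalings, no variance trend, leaving out each library and, for lists, the estimated correlation and shared genes left out.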

Results

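Bulk RNA sequencing compared 2 populations of coronary endothelial cells, the cells that line the vessels of the heart, from zebrafish ventricles at 7 days after cryoinjury, a freezing injury from which the zebrafish heart regrows muscle. Wild-type cells carrying a red flt1 reporter were sorted by the presence or absence of a yellow reporter of cxcr4a, a chemokine receptor gene of growing vessels. The design names the compared populations regenerating and non-regenerating. The table heads its columns Regenerating (2 libraries) and Non-Regenerating (2 libraries), and the text uses these headings. The labels do not state which gate is which. Regenerating was taken as the cxcr4a-reporter-positive gate from knowledge of the reporter lines, before any gene's values were examined. Each library was made from about 5 ng of total RNA. The normalized counts summed to 10662434 and 10481747 in the Regenerating libraries and to 10761712 and 10564201 in the Non-Regenerating libraries. The reads behind them were estimated at 11583307, 10550324, 10841942 and 9741978 in the same order. Nothing in the labels says whether the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

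The question of the comparison was which genes differ between regenerating and non-regenerating coronary endothelial cells. The B-cell antibody gene ighv1-4 was the only one of 16928 genes tested that was called, at 2365 ± 274 normalized counts in Regenerating and 4.5 ± 0.707 in Non-Regenerating (SD, n = 2 each). The cxcr4a gene, whose reporter defined the gates, read 2264 ± 30.4 in Regenerating and 587.5 ± 3.54 in Non-Regenerating, 3.85-fold higher. The transcript of gpnmb, a membrane glycoprotein of macrophages and other cells that the series title names, read 3390 and 4646 in the Regenerating libraries and 110 and 15 in the Non-Regenerating libraries, 94.2-fold higher on the log2(value + 1) scale, with a log2 fold change of 5.16 without Non-Regenerating replicate 2 and 7.96 without Non-Regenerating replicate 1. The flt1 gene, which encodes a receptor of vascular endothelial growth factor and whose reporter selected all cells, read 5711 ± 303 in Regenerating and 6622 ± 38.2 in Non-Regenerating. With limma and Benjamini-Hochberg adjustment, ighv1-4 (ENSDARG00000096355, chromosome 3, 33963247 to 34095221, danRer11) had a log2 fold change of 8.75 (SE 0.314, adjusted p = 0.0157), or 7.35 with a pseudocount of 10. The gene cxcr4a (ENSDARG00000057633, chromosome 6, 12922002 to 12923727) had 1.94 (SE 0.137, adjusted p = 0.0949), and gpnmb (ENSDARG00000062688, chromosome 19, 20247435 to 20270207) had 6.56 (SE 0.908, adjusted p = 0.161). The gene flt1 (ENSDARG00000019371, chromosome 24, 21750810 to 21808819) had -0.21 (SE 0.0922, adjusted p = 0.436). At an unadjusted p under 0.05 there were 2168 genes, 1290 higher and 878 lower in Regenerating, and 5 genes had an adjusted p under 0.1. In 43.2% of tested genes the libraries of the groups did not overlap, against 33.3% by chance. Without any 1 of the 4 libraries, or without the variance trend, limma called no gene, with 1147 to 2101 genes at an unadjusted p under 0.05 when a library was left out and 2026 without the trend. The annotated span of ighv1-4 overlaps 25 other genes of the table on the same strand, so reads may be shared among antibody gene segments and its value is uncertain as that of a single gene.

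**Figure D1:**
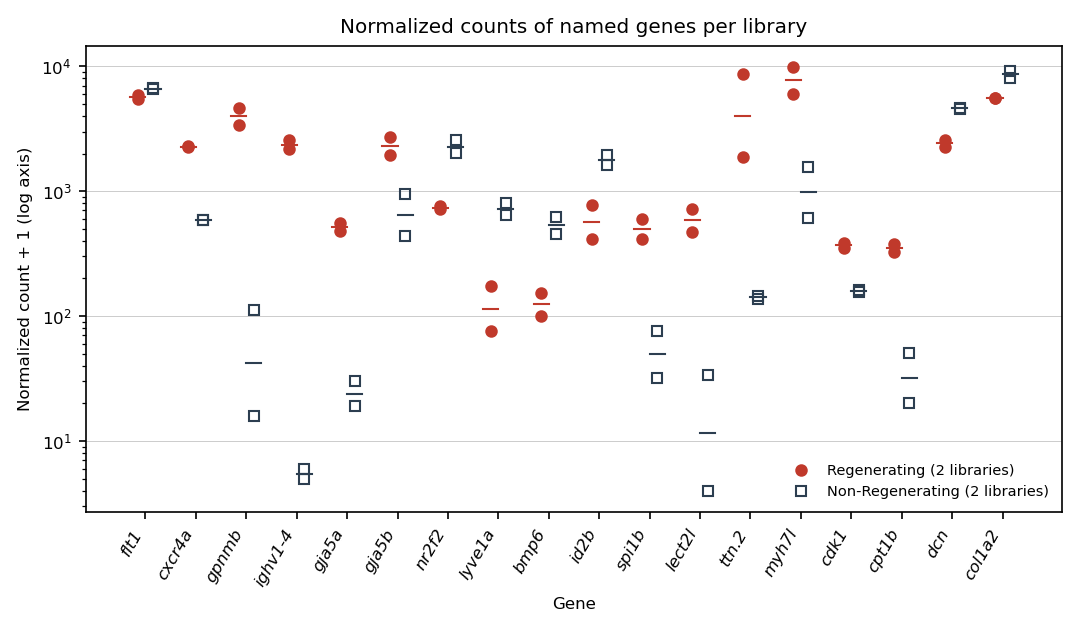
Normalized count plus 1 (log axis) in each library for 18 named genes, with filled circles for the 2 Regenerating libraries, open squares for the 2 Non-Regenerating libraries and a short line at each group's mean of log2(value + 1). The Regenerating libraries read 2285 and 2242 for cxcr4a against 585 and 590, and the flt1 values of all 4 libraries lie between 5496 and 6649.

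Among vessel-type genes, 2 connexin genes of arterial endothelium were higher in Regenerating, while 3 of 14 venous and lymphatic markers and 6 of 19 markers of endocardium, the inner lining of the heart, were lower and 1 endocardial marker was higher, adjusted over each list alone. The venous and lymphatic list and the endocardial list were called lower by camera, but not with an estimated correlation (adjusted p = 0.336 for each). In the arterial and Notch list, 2 of 18 tested members were higher and 1 was lower when adjusted over the list alone, and 15 did not pass. The connexin gene gja5a read 517 ± 47.4 against 23.5 ± 7.78, 21.6-fold higher, and gja5b 2325 ± 529 against 696 ± 363. The netrin receptor gene unc5b was lower, at 5 ± 1.41 against 49 ± 1.41. The list as a whole was not called by camera (adjusted p = 0.0543, or 0.645 with an estimated correlation). It was called higher without Regenerating replicate 1 (0.0344), without Non-Regenerating replicate 2 (0.00913), without the low-value filter (0.0485), with a filter of 50 (0.01) and with quantile scaling (0.00635). The venous and lymphatic list had a camera adjusted p of 1.55e-04 (adjusted p = 0.336 with an estimated correlation) and a median log2 fold change of -0.41, over members from -3.20 to 1.98. The 3 that were lower were nr2f2, a transcription factor of vein identity (738 ± 26.2 against 2274 ± 383), the lymphatic marker lyve1a (124 ± 69.3 against 723 ± 120) and the ephrin receptor gene ephb4b (3577 ± 21.2 against 4943 ± 113). The endocardial list had a camera adjusted p of 2.92e-05 (adjusted p = 0.336 with an estimated correlation) and a median of -0.33, over members from -4.27 to 0.86. The growth factor gene bmp6 was 4.27-fold lower, id2b, a target of that pathway, 3.14-fold lower. The neuregulin gene nrg2a read 52 and 23 against 788 and 250, a log2 fold change of -3.64 that was -2.82 without Non-Regenerating replicate 1 and -4.47 without Non-Regenerating replicate 2. The cardiac transcription factor genes gata4 and gata5, chosen after their values were seen, were also among the 6, and the activin gene inhbaa was the higher one. A second activin gene, inhbab, is not in the list and was chosen after its values were seen. It went the other way, at 17 and 12 against 461 and 139. The endocardial median was -0.66 without Non-Regenerating replicate 2. The venous and lymphatic median was -0.61 without Regenerating replicate 1, and both remained called by camera without any 1 library.

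In these values the general endothelial markers differed little between the groups. Whether reads of these abundant genes were near a ceiling, which would hide a difference, stays open. The pan-endothelial list had 21 of 26 members below 0 and a median of -0.08, was called lower by camera (adjusted p = 0.00931) and had no member that passed adjustment over the list alone. The adjusted p of this list was 0.645 with an estimated correlation. The clotting factor carrier vwf read 5057 ± 1317 against 11485 ± 2638, tek 5023 ± 478 against 6350 ± 93.3 and erg 1024 ± 169 against 1364 ± 58.7. The adjusted p of the list was 0.223 without Regenerating replicate 1 (median -0.02) and 0.509 without Non-Regenerating replicate 2 (median -0.02), so the call rested on these libraries. It was 0.194 with quantile scaling (median -0.05) and 0.0992 without the variance trend. The median was -0.14 without Regenerating replicate 2 and -0.15 without Non-Regenerating replicate 1. Random lists of genes with matching mean expression had a median of -0.08, and 46.9% of 10000 such lists had a median at least as low. The tip cell and angiogenic sprouting list was not called (adjusted p = 0.241, or 0.645 with an estimated correlation), but 4 of its 27 members were higher when adjusted over the list alone. The chemokine receptor gene cxcr1 read 460 ± 199 against 5.5 ± 7.78, the placental growth factor gene pgfb 468 ± 165 against 145 ± 15.6 and esm1, a secreted product of sprouting tips, 1609 ± 189 against 800 ± 165. The list was called with quantile scaling (adjusted p = 0.0361). The receptor cxcr1 is also expressed by neutrophils.

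The lymphoid, macrophage and neutrophil lists were called higher in Regenerating. In the lymphoid list, 4 of 8 tested members were higher when adjusted over the list alone and none lower. The row with the symbol ighv1-4 entered this list by gene identifier, since ighm and ighz are the only antibody genes that the list names. Besides ighv1-4, the B-cell receptor gene cd79b read 50 and 36 against 0 and 0, at least 13.8-fold higher against a floor of 3 reads per library. The B-cell transcription factor gene pax5 read 13 and 17 against 0 and 0, at least 4.81-fold higher, which is a counting limit only. The list was called higher by camera (adjusted p = 2e-04, median 2.01), with an adjusted p of 0.336 with an estimated correlation and 0.00506 by fry. Only 8 of its 13 found members passed the low-value filter. Among these, ighv1-4, cd79b and pax5 passed only through the Regenerating libraries, so their direction was fixed by entry and the tests overstate the support. Setting both genes to these bounds left the median at 2.01, which is little of a check, since both bounds still lie above it. The lymphoid median was 1.13 without the low-value filter (camera adjusted p = 0.0104) and 1.15 with a pseudocount of 10. It was 3.57 with a filter of 50, where the list was no longer called (0.185). The macrophage and monocyte list was higher (adjusted p = 0.00175, median 0.91) with 3 of 23 members higher when adjusted over the list alone, namely gpnmb, the myeloid transcription factor gene spi1b (504 ± 132 against 53 ± 31.1) and the leukocyte phosphatase gene ptprc (633 ± 66.5 against 128 ± 89.8). Its adjusted p was 0.645 with an estimated correlation, and without Non-Regenerating replicate 2 it was 0.245 with a median of 0.04. The median was 0.60 without Regenerating replicate 1 and 1.47 without Non-Regenerating replicate 1. The neutrophil list was higher (adjusted p = 0.0194, median 0.82), with lect2l (595 ± 175 against 18 ± 21.2), adam8a and mmp25b passing when adjusted over the list alone. This call had an adjusted p of 0.452 with an estimated correlation, 0.0625 without Regenerating replicate 2 and 0.0888 without Non-Regenerating replicate 2 (median 0.27). It was 0.0945 without the low-value filter and 0.107 with a filter of 50, both with a median of 0.40, and the median was 0.45 without Regenerating replicate 1. The erythrocyte and thrombocyte list had 6 members tested and was not called (adjusted p = 0.146, median -1.18). Its median was -0.68 without Regenerating replicate 1 and without Non-Regenerating replicate 1, -0.79 without Non-Regenerating replicate 2, -0.39 without the low-value filter and -0.31 with a filter of 50. No member passed there when adjusted over the list alone, and f13a1a.1 read 5 and 17 against 802 and 11. The lysosome list was not called (adjusted p = 0.2), with gpnmb and the lysosomal channel gene mcoln1a (848 ± 192 against 245 ± 22.6) higher when adjusted over the list alone. It was called without Regenerating replicate 1 (0.0451), without Non-Regenerating replicate 1 (0.0435) and with quantile scaling (0.0432). The inflammatory cytokine and adhesion list (adjusted p = 0.624) and the interferon response list (adjusted p = 0.262) were not called. Each had 1 member lower when adjusted over the list alone, the adhesion receptor gene sele (4467 ± 170 against 7078 ± 25.5) and the antiviral gene rsad2 (165 ± 21.9 against 474 ± 13.4).

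Heart muscle transcripts were higher in both Regenerating libraries, with a wide difference between these. The cardiomyocyte list had 17 of 22 members higher when adjusted over the list alone and none lower (camera adjusted p = 5.97e-12, median 2.65). The adjusted p of the list was 0.452 with an estimated correlation. The giant sarcomere protein gene ttn.2 read 8591 and 1884 against 137 and 144, myom1b, an M-band protein gene, 3173 and 981 against 124 and 60, and the myosin gene myh7l 9899 and 5990 against 1559 and 612. The genes ttn.2 and ttn.1, and likewise myh7l and myh7, are close copies, so their separate values are uncertain. All 22 members were higher in Regenerating replicate 1 than in Regenerating replicate 2, with a median ratio of 2.57. The mural cell list, markers of smooth muscle and pericytes, was not called (adjusted p = 0.601, median 0.02) with 1 of 16 members, smooth muscle myosin gene myh11a, higher when adjusted over the list alone (7857 ± 141 against 3664 ± 517). Its median was -0.90 without Regenerating replicate 1 and 1.14 without Regenerating replicate 2, with camera adjusted p of 0.0349 and 0.00105 in opposite directions.

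The epicardial and fibroblast list was lower in Regenerating (camera adjusted p = 0.0115, median -0.38), with 6 of 22 members lower and 2 higher when adjusted over the list alone. It had an adjusted p of 0.452 with an estimated correlation. The proteoglycan gene dcn was 1.90-fold lower, and the collagen I genes col1a2 and col1a1a were 1.54-fold and 1.65-fold lower. The 2 that were higher were the matrix genes postnb and fn1b. The list had an adjusted p of 0.0509 without Regenerating replicate 1 and 0.102 without the variance trend, and its median was -0.22 without Non-Regenerating replicate 1. The extracellular matrix and basement membrane list was not called (adjusted p = 0.189), but was called lower without Regenerating replicate 1 (0.0365). Its member lama5 was lower when adjusted over the list alone, at 85 ± 12.7 against 423 ± 16.3, and the laminin gene lamb2 read 454 ± 186 against 130 ± 12.7. The mesenchymal transition list was not called (adjusted p = 0.624, median -0.03 and mean 0.06, with medians of -0.39 without Regenerating replicate 1 and 0.40 without Regenerating replicate 2), with 3 of 23 members higher when adjusted over the list alone. These were the intermediate filament gene vim (1283 ± 170 against 429 ± 39.6), prrx1a and postnb. The TGF-beta and BMP signalling list was not called (adjusted p = 0.0644) and had no member that passed when adjusted over the list alone. Its members id2b, tgfbr2a (233 ± 11.3 against 470 ± 82.7) and ltbp1 had the smallest unadjusted p. Without Non-Regenerating replicate 1 its adjusted p was 0.00892, and without Regenerating replicate 2 it was 0.0412.

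The cell cycle list and the fatty acid list were called higher in Regenerating by camera, but not with an estimated correlation (adjusted p = 0.452 for each). The cell cycle list had 29 of 36 members above 0 and a median of 0.62 (camera adjusted p = 2e-04), but no member passed when adjusted over the list alone. Its median was 0.38 without Regenerating replicate 1. The lymphoid, macrophage, neutrophil and cardiomyocyte lists were higher in the same comparison, with medians of 2.01, 0.91, 0.82 and 2.65. The mitotic kinase gene cdk1 read 368 ± 22.6 against 158 ± 2.83, cenpe 152 ± 40.3 against 56 ± 14.1 and the cyclin gene ccnb1 142 and 125 against 63 and 53. The fatty acid uptake and metabolism list was higher (adjusted p = 6.67e-04, median 0.41), with cpt1b, a mitochondrial fatty acid importer gene of muscle (350 ± 36.8 against 34.5 ± 21.9), and angptl4 (2889 ± 224 against 1603 ± 151) among its 24 members higher when adjusted over the list alone. The cardiomyocyte list moved in the same direction, and fabp3, a fatty acid binding protein gene of muscle, read 934 and 368 against 209 and 85. The gene cpt1b, however, read 324 and 376 against 19 and 50. It was thus not higher in Regenerating replicate 1, as all 22 cardiomyocyte members were. The hypoxia and glycolysis list was not called (adjusted p = 0.241), and ca9, pfkfb3 and gpib had the smallest unadjusted p among its 33 members, none passing when adjusted over the list alone. The immediate early and dissociation stress list was not called (adjusted p = 0.0961, median -0.09), with nr4a1 at 3599 ± 131 against 4865 ± 156. It was called lower without Non-Regenerating replicate 1 (0.00429, median -0.16), and the median was -0.03 without Non-Regenerating replicate 2. The ribosomal protein list was lower (adjusted p = 8.38e-10, median -0.21), with 80 of 83 members below 0 but none passing when adjusted over the list alone. The ribosomal protein call had an adjusted p of 0.336 with an estimated correlation and 0.0271 by fry. Of 23 lists tested, 11 were called by camera with the preset correlation, 6 higher and 5 lower, and none with an estimated correlation, where 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.336. By fry, 2 lists were called for direction.

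**Figure D2:**
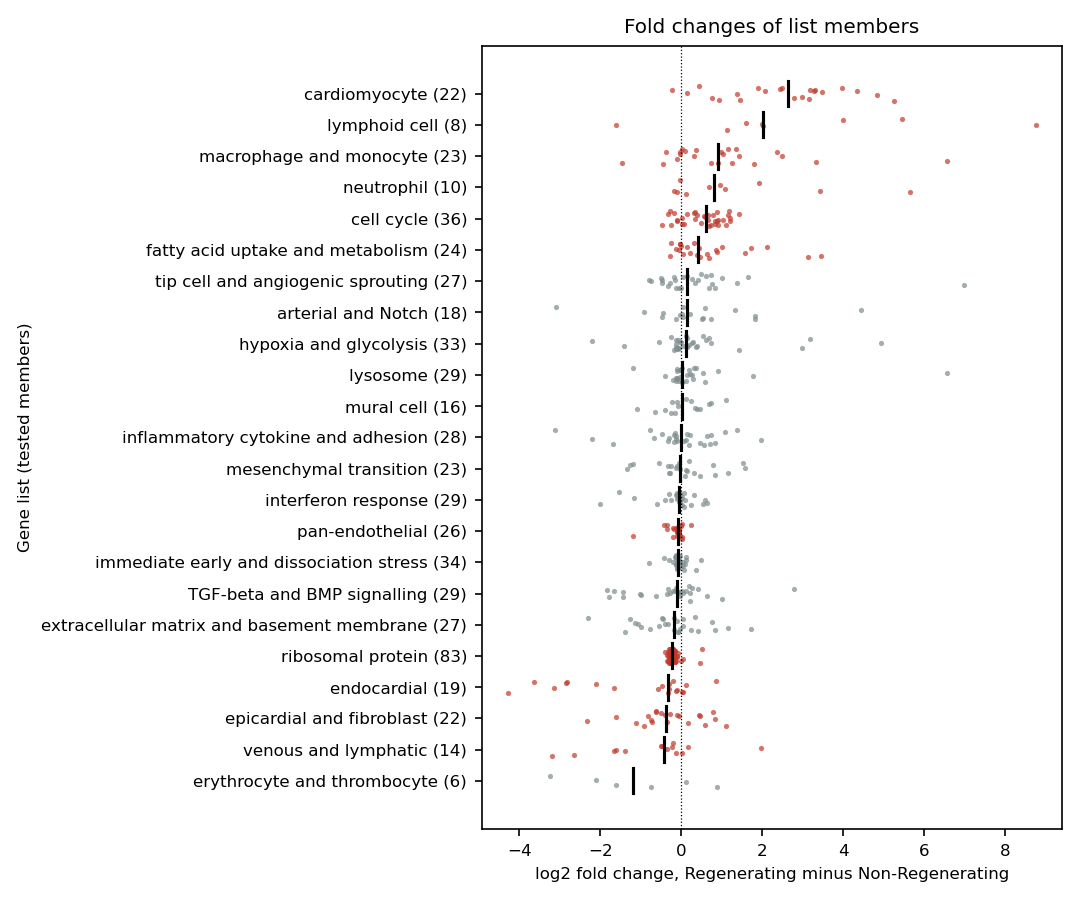
Log2 fold change (Regenerating minus Non-Regenerating) of each tested member of the 23 gene lists, with list sizes in parentheses, black bars at the medians and red points for lists called by camera with the preset correlation. The medians run from -1.18 in the erythrocyte and thrombocyte list to 2.65 in the cardiomyocyte list.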

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

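The counts below depended on the processing as follows. The 1 called gene, ighv1-4, remained called without the filter, with a filter of 50, with pseudocounts of 0.1 and 10, with TMM or quantile scaling and with a log2 fold change of at least 1. The count was 0 without the variance trend and 0 leaving out each library in turn, where the spread of a lone library is assumed to be that of the other group; the cause was not tested beyond the smaller number of libraries. With the replicate number as a replicate block, 357 genes were called, but the labels do not say that the numbers pair the libraries, and with 2 pairs this cannot be established. Deviations of same-numbered libraries correlated across genes with r = 0.34. The number of called lists, 11 in the chosen fit, was 0 with the estimated correlation and 9 to 14 leaving out each library, of which 8 to 11 were among the original 11. With the replicate block 13 lists were called, adding arterial and Notch (adjusted p = 0.0447) and immediate early and dissociation stress (0.049). The direction of camera's test, which follows the members' statistics and can differ in sign from the median, turned in 3 lists that were not called in the chosen fit. It turned from higher to lower in the mural cell list without Regenerating replicate 1 (median -0.90) and without Non-Regenerating replicate 2 (-0.56), over medians of -0.90 to 1.14 without single libraries. It turned from higher to lower in the mesenchymal transition list with shared genes left out (-0.11), without Regenerating replicate 1 (-0.39) and without Non-Regenerating replicate 2 (-0.09), although the median was already -0.03, over medians of -0.39 to 0.40. It turned from lower to higher in the inflammatory cytokine and adhesion list without Non-Regenerating replicate 1 (0.0721), over medians of -0.13 to 0.0721; the cause was not tested. The sign of a list's median alone changed in further cases, among them the inflammatory list without Regenerating replicate 2 (0.0456), without the low-value filter (0.12) and with quantile scaling (0.0126), and the mesenchymal list without Regenerating replicate 2 (0.40), without Non-Regenerating replicate 1 (0.28) and with a filter of 50 (0.0369). All 822 values of the 69 named genes under these alternatives kept their direction, 26 became called, all under the replicate block (among them cxcr4a with adjusted p = 0.0133 and gpnmb with 0.0417), and 5 lost their call. For every named gene but f13a1a.1 the groups did not overlap. Their direction could turn only under TMM or quantile scaling, so under the other alternatives it was fixed in advance. The planned edgeR and DESeq2 fits were not run, because the deposited values are rounded normalized counts. Depth limits genes near the floor of 3 reads.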

Other observations

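All genes in this paragraph and the next were chosen after their values were seen. Antibody genes moved together with ighv1-4. All 11 tested immunoglobulin gene segments were higher in both Regenerating libraries than in both Non-Regenerating libraries. Each had passed the filter only through values of at least 10 in both Regenerating libraries, so this separation was fixed in advance. Segments that failed the filter are not counted. Summed normalized counts of the 11 were 3590 and 2955 against 8 and 5, and 7 of them were at 0 in both Non-Regenerating libraries. The segments differed between the Regenerating libraries. The light-chain gene igl3v3 read 19 and 220, igl3v1 read 241 and 16 and ighv9-1 read 144 and 11, while igl3v5 read 226 and 240. Reads may be shared among such segments, so the values of single segments are uncertain. In the same table the lymphoid gene cd28 went the other way, at 67 and 112 against 447 and 157, with adjusted p = 0.0653 over the lymphoid list alone (limma), and the sort had selected endothelial cells.

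Apart from the genes named by rule and those with provisional names, 248 genes had an unadjusted p under 0.005, a mean of at least 200 in the higher group and no overlap between groups, of which 142 were higher and 106 lower in Regenerating. Among the lower ones were bmp10, a growth factor of the heart (33 and 26 against 1161 and 347), the transcription factor gene sall1a (400 and 288 against 5251 and 2047), the axon guidance gene ntn1b (203 and 51 against 3590 and 1598) and the Wnt agonist gene rspo2 (48 and 7 against 555 and 563). The matrix cross-linking enzyme gene loxl1 read 1330 and 891 against 6736 and 7432, the receptor gene gpr182 read 451 and 217 against 1947 and 1685, and the growth factor binding protein gene igfbp6b read 245 and 180 against 2052 and 1782. Among the higher ones were the chemokine receptor gene ccr9a (1456 and 2378 against 213 and 51), the integrin gene itgae.2 (330 and 326 against 25 and 30) and the protocadherin gene pcdh19 (670 and 561 against 51 and 94). Heart and muscle genes were among them too, such as xirp1 (2941 and 528 against 77 and 17), casq2 (1671 and 433 against 85 and 28), actn2b (4387 and 1594 against 408 and 196) and tcap (1391 and 597 against 131 and 74), alongside the higher cardiomyocyte list. None of these passed limma's adjusted p of 0.05.

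The tests of explanations in the rest of this part were chosen after the results they bear on were seen. The fits without single libraries, with an estimated correlation and with shared genes left out had been fixed before the data were examined. The pan-endothelial list was lower in Regenerating, with a median log2 fold change of -0.08. If the reads of these abundant genes are near a ceiling in every library, division by the size factors would set their values, and within each group the library with the smaller size factor would read higher by a log2 of 0.119 on average, with Regenerating against Non-Regenerating at -0.12. The observed within-group difference was 0.130 with a standard error of 0.0137, but the difference between the groups lay further from the -0.12 than 2 of its standard errors (0.0149). Both errors treat the list's genes as independent, although their estimated correlation was 0.528, so they are too small to settle this. The authors' scaling of capped reads stays open. Of random lists with matching expression, 46.9% had a median as low, which a trend over abundance would give. The draws did not leave out the list's own genes or other endothelial genes. A shared fall of abundant endothelial transcripts could therefore give the same share, and the draws do not separate these. The ribosomal protein list was lower, with a median of -0.21. Its within-group difference was 0.00248 with a standard error of 0.0054, which argues against fully capped reads as the cause. This error too treats genes as independent, at an estimated correlation of 0.0483. Its expression-matched lists had a median of -0.0246, which argues against a trend over abundance as these values measure it. Reads compressed only in part were not tested. A biological difference between the gates stays open for the ribosomal protein genes and was not tested.

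The gpnmb transcript was higher by a log2 of 6.56, or 5.16 without Non-Regenerating replicate 2. The macrophage list, gpnmb included, was called higher, but not with an estimated correlation (adjusted p = 0.645) or without Non-Regenerating replicate 2 (0.245), and it was called with gpnmb and lgmn left out (0.00423, median 0.91). A lower share of endothelial RNA would raise the markers of every other cell type alike, but the epicardial and fibroblast list had a median of -0.38, and of -0.22 to -0.40 without single libraries. The erythrocyte and thrombocyte median was -1.18 and the mural cell median 0.02. The cardiomyocyte, lymphoid and neutrophil medians were 2.65, 2.01 and 0.82. More macrophages with the same mix of transcripts would raise the other 22 macrophage genes by as much only if macrophages alone supplied them. Their median was 0.82, the highest, spi1b, was at 3.33 and mpeg1.2 was at -1.45. Supply of these genes by other sorted cells was not measured, so these values do not decide it. More macrophages, a myeloid population with much gpnmb and expression of gpnmb by endothelial cells of the Regenerating gate all stay open. The cells were sorted by the flt1 reporter, and the leukocyte gene ptprc was still read, at 586 and 680 in Regenerating against 191 and 64 in Non-Regenerating. How many myeloid cells passed the gate was not measured, and these bulk libraries do not separate the explanations.

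The cardiomyocyte list was higher by a median of 2.65. Without Regenerating replicate 1 the median was 1.80 with camera adjusted p = 2.5e-08, and 19 of 22 members were higher in Regenerating replicate 2 than in both Non-Regenerating libraries, which argues against that library alone as the whole cause. With an estimated correlation the list was not called (adjusted p = 0.452). Cardiomyocyte RNA carried into the sort in an amount that differs between libraries would move all its genes together within a group, and 22 of 22 members were higher in Regenerating replicate 1 than in Regenerating replicate 2, where 49.5% of all tested genes were. Carried-over RNA, which may also have differed between the gates, would give this. Muscle genes expressed together by the sorted cells would too, so the count does not separate them. In Non-Regenerating, 17 of the 22 were higher in replicate 1. Expression of muscle genes by the sorted cells stays open and was not tested.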
